A study of Mus musculus with 12 samples.

How the data were processed

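The series holds 12 libraries of mouse RNA, 3 each of bone marrow and lung from mice transplanted with AML cells and from mice not transplanted. Per the labels, the cells were VE-cadherin-positive endothelial cells, total RNA was taken with a micro-scale column kit, and libraries were made with kits for very low RNA input. Per the submitters' processing notes, reads were handled with bcl2fastq and STAR on the mm10 build, and versions are not given in the sources used here. The gene annotation, the counter and the read filters are not given in the sources used here either. The deposited files hold 1 raw count per gene symbol and library, as whole numbers from 0, and the authors applied no normalisation to them. Per the file names, counting ignored the strand, so overlapping and antisense genes cannot be told apart. Each file listed the same 55291 symbols, and gene positions came from the GENCODE annotation of GRCm38.

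Total counts per library lay between 12.8 and 39.2 M counts. Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and figures were drawn with matplotlib. The main test was the edgeR quasi-likelihood F test on all 12 libraries in 1 model with the 4 groups, with robust dispersion estimates and 8 residual degrees of freedom. Genes were kept by the edgeR expression filter by group (minimum count 10, minimum total 15), which left 18147, and libraries were scaled by TMM factors of 0.865 to 1.25. The comparisons were marrow AML against marrow control, lung AML against lung control, the difference of these 2 effects as an interaction, and marrow control against lung control. A gene was called at an adjusted p (Benjamini-Hochberg over all genes tested) under 0.05. Values in CPM are TMM-scaled counts, given as mean and SD over 3 libraries, and log2 fold changes are fitted values with their standard error. Where a group had 0 counts, a bound was computed against a floor of 3 counts over the group, and with 1 to 3 counts the ratio was given with its 95% counting interval. Logarithms of single-library values used a prior count of 2.

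Each of 37 gene lists was tested with camera at its preset correlation of 0.01, with p-values adjusted over the 37 lists of a comparison. The lists for cell types and vessel states were pan-endothelial, marrow sinusoidal endothelium, arterial endothelium, venous endothelium, lung aerocyte capillary, lung general capillary and lymphatic endothelium. Pathway, process and protein class lists were niche factors, interferon response, antigen presentation, inflammatory activation and adhesion, hypoxia and glycolysis, angiogenic sprouting, basement membrane and matrix, cell proliferation, p53 targets, oxidative phosphorylation, cholesterol synthesis, fatty acid handling, Notch pathway, TGF-beta response and mesenchymal transition, coagulation and haemostasis, flow response, immediate early genes, unfolded protein response and cytosolic ribosomal proteins. Lists for other cells of marrow and lung were pan-leukocyte, myeloid progenitor and blast, neutrophil, monocyte and macrophage, erythroid, megakaryocyte and platelet, B cell, T and NK cell, marrow stromal and osteolineage, pericyte and smooth muscle and lung epithelium. Of the 15 erythroid genes listed, 14 were in the files. Genes were named by a rule. Per comparison it took the 8 largest rises and the 8 largest falls among called genes with a mean of at least 10 CPM in the higher group and no overlap between the groups. Symbols of predicted genes, clones, immune receptor segments and pseudogenes were passed over, and for the interaction the overlap condition was dropped. It also took up to 4 tested members with the smallest p of each list described, and Cdh5, Pecam1 and Ptprc throughout, and a list member it took in the marrow is not reported here, for a reason unrelated to its value. Other genes named are said to have been chosen after their values were seen. Groups, tests, lists, the naming rule and the alternatives below were set before the data were examined, except where the text says otherwise.

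Alternatives for the gene tests were DESeq2 size factors in edgeR, TMM factors without the genes of the blood cell lists, the DESeq2 Wald test, and limma-voom with sample quality weights. Others were no filter, a filter of 5 CPM in 3 libraries, dispersion estimates without the robust option, a test against a 1.5-fold change, a replicate block, a fit of only the 6 libraries compared, and leaving out each library in turn. Scaling by library totals alone was added after seeing the data. What each explanation of a pattern should give was set with the values known, except for the splits of the libraries, and the tests of lung epithelium and of the endothelial share replaced earlier ones that could not separate the explanations. For the lists, camera with an estimated correlation, fry, a replicate block and leaving out each library were tried. Whether replicate numbers pair libraries across groups was checked on residuals, and correlations of libraries with the same number lay between -0.231 and 0.279, so the numbers were not used as pairs in the main test. Replicates were checked for repeated sequencing of 1 library, and the chi-square per degree of freedom between replicates was 36.4 to 183, where repeats would give about 1.

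The steps were tested on simulated data built on these libraries, with 100 genes changed 2-fold and 100 changed 4-fold per comparison. Of the changed genes tested, 12.4% of the 2-fold and 51.0% of the 4-fold ones were recovered in the marrow comparison, and 6.25% and 42.6% in the lung comparison. For the interaction the shares were 0% and 8.33%, and for marrow control against lung control 1.03% and 47.3%. Unchanged genes called numbered 5, 0, 0 and 2 in that order, and 0 of 20 unchanged lists was called in each. All 12 libraries were used, and no sample was left out.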

Results

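Expression was measured by RNA sequencing of low-input libraries made, per the labels, from VE-cadherin-positive endothelial cells of the bone marrow and the lung of VECadCre-tdTomato mice, a line whose labelled cells express a red fluorescent protein. Mice had been transplanted with acute myeloid leukaemia (AML) cells carrying a mutant and a deleted allele of the tumour suppressor Trp53, or had not been transplanted. The 12 libraries formed 4 groups of 3, marrow control, marrow AML, lung control and lung AML. Total counts were 21.8, 21.4 and 17.0 M in marrow control libraries 1, 2 and 3, and 12.8, 21.0 and 24.8 M in the marrow AML libraries. They were 24.1, 27.2 and 28.6 M in the lung controls and 39.2, 27.0 and 26.2 M in the lung AML libraries. Of 55291 symbols, 18147 had enough counts to be tested. Spearman correlations across genes, which are not independent replicates, lay between libraries of a group from 0.970 to 0.974 in marrow controls and from 0.913 to 0.939 in marrow AML. The ranges were 0.959 to 0.971 in lung controls and 0.984 to 0.986 in lung AML, and the leading principal component, with 67.9% of the variance, parted marrow from lung. The labels do not say that replicates are separate mice, so the p-values measure the spread between these samples. Intervals and floors cover counting error only.

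Transcripts of endothelial cells took a small share of each library. The 20 pan-endothelial genes, among them Cdh5, which encodes VE-cadherin, held 0.0248% ± 0.00521 (SD, n = 3) of the counts in marrow controls, 0.0272% ± 0.00252 (SD, n = 3) in marrow AML, 0.539% ± 0.371 (SD, n = 3) in lung controls and 0.0625% ± 0.0375 (SD, n = 3) in lung AML. The highest single share, in lung control library 2, was 0.964% (exact Clopper-Pearson 95% interval 0.960% to 0.968%). Lung epithelium genes, which encode surfactant proteins and other products of alveolar and airway cells, held 18.0% ± 1.90 (SD, n = 3) in lung controls and 22.1% ± 1.13 (SD, n = 3) in lung AML, against 0.120% ± 0.113 (SD, n = 3) and 0.0965% ± 0.0900 (SD, n = 3) in marrow controls and marrow AML. Sftpc, surfactant protein C, alone took 13.6% ± 1.68 (SD, n = 3) of the counts in lung controls and 15.7% ± 1.38 in lung AML. Erythroid genes held 2.69% ± 0.137 (SD, n = 3) in marrow controls and 0.383% ± 0.282 (SD, n = 3) in marrow AML, against 0.0369% ± 0.00383 and 0.0286% ± 0.0116 in the lung groups. Marrow stromal and osteolineage genes held 1.98% ± 0.420 and 1.49% ± 0.0795 in marrow controls and marrow AML. Pericyte and smooth muscle genes held 0.0411% ± 0.0256 in marrow controls and 0.651% ± 0.416 in marrow AML.

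**Figure D1:**
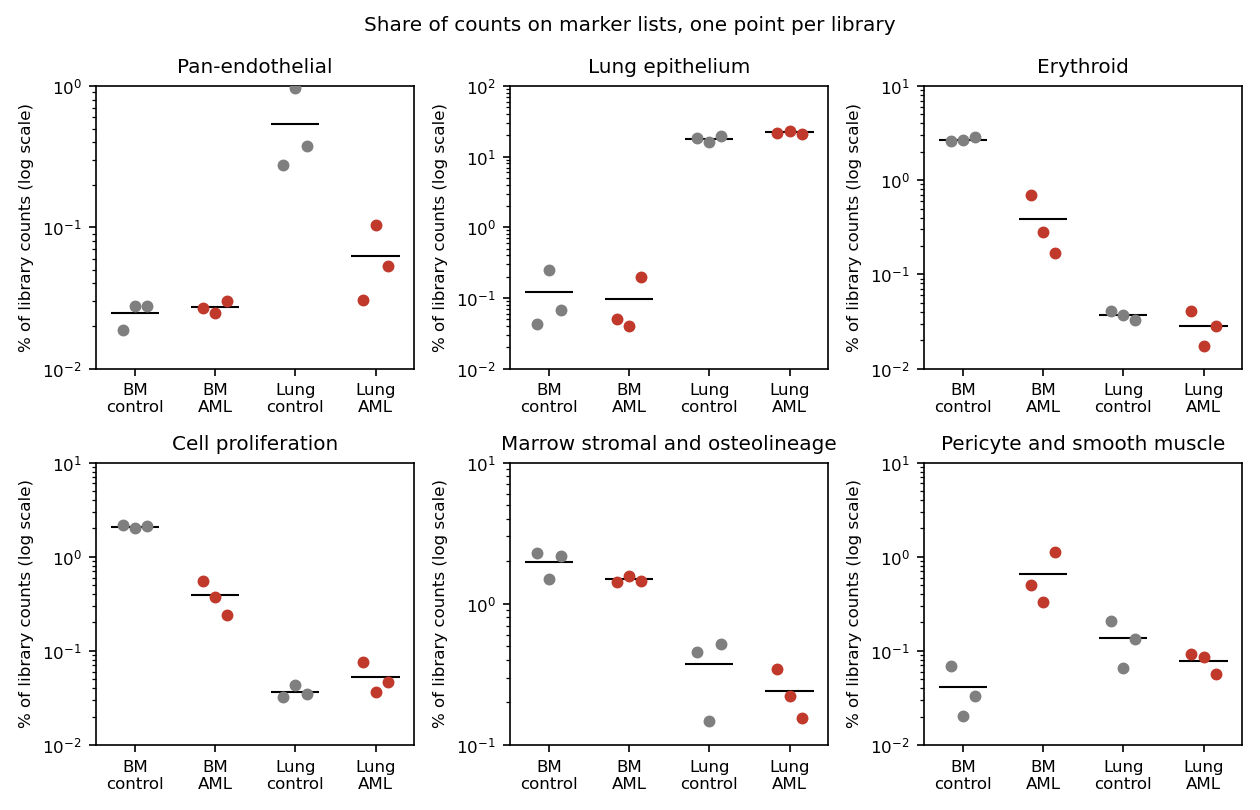
Share of library counts (%, log scale) on 6 marker lists, with 1 point per library and a line at each group mean. The pan-endothelial list averaged 0.539% of counts in lung controls and 0.0625% in lung AML, and the lung epithelium list 18.0% and 22.1%.

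Marrow AML libraries were compared with marrow controls, both low in endothelial transcripts. Camera called lists of erythroid and proliferation genes as lower, and of glycolysis, matrix, TGF-beta response, inflammatory activation and pericyte genes as higher. Erythroid and pericyte shares differed too, and cell makeup as the cause was not tested. With an estimated correlation between genes, only the hypoxia and glycolysis list kept its call, 1 of 15. Klf1, a transcription factor of red cell development, dropped from 836 ± 7.90 to 124 ± 41.9 CPM (counts per M counts, mean ± SD, n = 3; log2 fold change -2.75 ± 0.37, adjusted p = 0.000217). Pkm, which encodes a pyruvate kinase of glycolysis, rose from 68.2 ± 16.5 to 696 ± 28.2 CPM (log2 fold change 3.35 ± 0.21, adjusted p = 8.12e-06). Rgs5, a pericyte gene, rose from 38.5 ± 24.4 to 412 ± 148 CPM (log2 fold change 3.42 ± 0.53, adjusted p = 0.000482). By the edgeR quasi-likelihood test, 7957 genes passed an adjusted p of 0.05, 3694 higher and 4263 lower in AML, of 18147 tested. The balance of directions turned with the scaling and with the genes tested. The median log2 fold change of all genes was -0.11 with TMM and 0.16 with library totals alone, a setting chosen after seeing the data, under which 4651 genes were higher and 2943 lower. More genes were higher than lower also with a filter of 5 CPM in 3 libraries (3750 and 2833), with only the 6 libraries compared (2924 and 2543) and against a 1.5-fold change (2851 and 2778). The direction of the median of each list called below, in any comparison, was the same under all 4 scalings tried.

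Of 14 erythroid genes, 13 fell, with 14 adjusted over the list alone (median log2 fold change -3.79, camera adjusted p = 6.38e-06, or 0.355 with an estimated correlation). Next to Klf1 stood Car2, a carbonic anhydrase (log2 fold change -2.94 ± 0.42, adjusted p = 0.000317), Hemgn, a nuclear protein of blood precursors (log2 fold change -4.71 ± 0.84, adjusted p = 0.00109), and Epor, the erythropoietin receptor (log2 fold change -2.08 ± 0.37, adjusted p = 0.00113). Among 34 proliferation genes, 34 fell, against 34 adjusted over the list alone (median log2 fold change -2.73, camera adjusted p = 2.87e-15, or 0.275 with an estimated correlation). Examples were Hmgb2, a chromatin protein of dividing cells (log2 fold change -2.44 ± 0.22, adjusted p = 2.62e-05), and Pcna, the replication clamp (log2 fold change -2.37 ± 0.23, adjusted p = 3.31e-05). Of 43 oxidative phosphorylation genes, 25 fell, with 29 adjusted over the list alone (median log2 fold change -0.70, camera adjusted p = 0.000138, or 0.690 with an estimated correlation). Uqcrfs1, a subunit of respiratory complex III, fell (log2 fold change -1.41 ± 0.17, adjusted p = 0.000102). Among 38 ribosomal protein genes, 18 fell, against 18 adjusted over the list alone (median log2 fold change -0.75, camera adjusted p = 0.00213, or 0.773 with an estimated correlation).

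Low-oxygen and glycolysis genes mostly rose. Of 29 hypoxia and glycolysis genes, 21 rose and 2 fell, with 21 and 2 adjusted over the list alone (median log2 fold change 1.59, camera adjusted p = 5.00e-09, or 0.0128 with an estimated correlation). Besides Pkm, it held Bnip3, a mitochondrial protein induced by low oxygen (log2 fold change 3.98 ± 0.30, adjusted p = 1.50e-05), and Aldoa, an aldolase (log2 fold change 2.37 ± 0.19, adjusted p = 1.68e-05). Among 28 TGF-beta response and mesenchymal transition genes, 21 rose and 1 fell, against 21 and 1 adjusted over the list alone (median log2 fold change 1.87, camera adjusted p = 3.01e-08, or 0.0945 with an estimated correlation). They included Id2, an inhibitor of DNA binding (log2 fold change 2.30 ± 0.21, adjusted p = 2.64e-05), Ccn2, a matricellular growth factor (log2 fold change 3.42 ± 0.34, adjusted p = 3.93e-05), and Vim, vimentin (log2 fold change 3.07 ± 0.40, adjusted p = 0.000169). Of 28 basement membrane and matrix genes, 17 rose and 2 fell, with 18 and 2 adjusted over the list alone (median log2 fold change 1.72, camera adjusted p = 1.26e-06, or 0.179 with an estimated correlation). Lama5, a laminin chain, had a log2 fold change of 3.94 ± 0.33 (adjusted p = 1.92e-05) and Col18a1, a basement membrane collagen, 3.47 ± 0.40 (adjusted p = 9.16e-05). Among 14 pericyte and smooth muscle genes, 12 rose, against 12 adjusted over the list alone (median log2 fold change 3.55, camera adjusted p = 2.82e-06, or 0.339 with an estimated correlation). Notch3, a receptor of mural cells, rose (log2 fold change 3.38 ± 0.50, adjusted p = 0.000378), as did Tagln, a smooth muscle actin-binding protein (log2 fold change 4.48 ± 0.71, adjusted p = 0.000531).

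Inflammatory, early-response and further lists were called as higher in marrow AML, but none of them with an estimated correlation. Of 27 inflammatory activation and adhesion genes, 19 rose and 3 fell, with 19 and 3 adjusted over the list alone (median log2 fold change 2.44, camera adjusted p = 8.49e-07, or 0.0736 with an estimated correlation). Tnfaip3, an inhibitor of NF-kappaB signalling, went from 183 ± 44.6 to 1322 ± 222 CPM (log2 fold change 2.85 ± 0.26, adjusted p = 2.64e-05). Among 27 immediate early genes, 21 rose and 3 fell, against 21 and 3 adjusted over the list alone (median log2 fold change 1.89, camera adjusted p = 4.89e-09, or 0.179 with an estimated correlation). Fos, a subunit of the AP-1 transcription factor, had a log2 fold change of 2.77 ± 0.28 (adjusted p = 4.47e-05). Of 27 niche factor genes, 14 rose and 3 fell, with 14 and 3 adjusted over the list alone (median log2 fold change 1.07, camera adjusted p = 0.00183, or 0.179 with an estimated correlation). These rising members included Igfbp3, a binding protein of insulin-like growth factors (log2 fold change 5.63 ± 0.59, adjusted p = 4.84e-05), Angpt2, a ligand of the Tie2 receptor (log2 fold change 4.09 ± 0.44, adjusted p = 5.93e-05), and Il6, a cytokine (log2 fold change 6.13 ± 0.75, adjusted p = 0.000122). Among 24 angiogenic sprouting genes, 13 rose and 4 fell, against 15 and 4 adjusted over the list alone (median log2 fold change 1.85, camera adjusted p = 0.00381, or 0.237 with an estimated correlation). Adm, the peptide adrenomedullin, had a log2 fold change of 4.89 ± 0.54 (adjusted p = 7.11e-05). Of 18 coagulation and haemostasis genes, 9 rose and 2 fell, with 9 and 2 adjusted over the list alone (median log2 fold change 1.33, camera adjusted p = 0.0122, or 0.275 with an estimated correlation). Among 12 aerocyte capillary marker genes, 7 rose and 1 fell, against 7 and 1 adjusted over the list alone (median log2 fold change 2.17, camera adjusted p = 0.0261, or 0.318 with an estimated correlation). Of that list, Emp2, a membrane protein, and Kitl, the Kit ligand, rose (log2 fold change 2.19 ± 0.20 and 2.32 ± 0.33, adjusted p = 2.41e-05 and 0.000318). Of 18 pan-leukocyte genes, 11 rose and 4 fell, with 12 and 4 adjusted over the list alone (median log2 fold change 1.96, camera adjusted p = 0.00216, or 0.275 with an estimated correlation).

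Endothelial identity genes were low in both marrow groups. Of 20 pan-endothelial genes, 2 rose and 7 fell, with 2 and 8 adjusted over the list alone, and the list was not called (median log2 fold change -1.64, camera adjusted p = 0.112). Of these genes, 11 had an unadjusted p under 0.05 by edgeR, and 11 passed by DESeq2 and 0 by limma-voom, so the edgeR calls of Cdh5 and Kdr below depend on the tool. Cdh5 (chromosome 8, 104101625 to 104144511, GRCm38) averaged 4.91 ± 1.51 CPM in controls and 0.634 ± 0.291 in AML (log2 fold change -2.90 ± 0.82, adjusted p = 0.0141). Kdr, a receptor of vascular endothelial growth factor, fell (log2 fold change -3.56 ± 0.70, adjusted p = 0.00186). Pecam1, an adhesion molecule of endothelium, and Ptprc, the pan-leukocyte phosphatase CD45, did not pass (log2 fold change -1.55 ± 0.80 and -1.53 ± 0.96, adjusted p = 0.139 and 0.219). Pecam1 passed without marrow AML 3 (log2 fold change -2.74, adjusted p = 0.0246) and with a replicate block (adjusted p = 0.0463), and Ptprc passed without marrow AML 2 (log2 fold change -5.01, adjusted p = 0.000236). Several lists were not called although members moved both ways, such as sinusoidal endothelium (camera adjusted p = 0.839), arterial endothelium (camera adjusted p = 0.104), venous endothelium (camera adjusted p = 0.839), interferon response (camera adjusted p = 0.0922) and p53 targets (camera adjusted p = 0.0818). Their median log2 fold changes were -1.93, 1.40, -1.04, -0.77 and 0.52 in that order. Counted gene by gene, 18 interferon response genes fell and 6 rose, with 18 and 7 adjusted over the list alone, and Rsad2, an antiviral enzyme, fell (log2 fold change -3.65 ± 0.51, adjusted p = 0.000267).

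The other lists not called in the marrow by camera, with median log2 fold changes, were general capillary (median -1.33, adjusted p = 0.775), lymphatic endothelium (median -0.73, adjusted p = 0.839), antigen presentation (median 0.01, adjusted p = 0.534), cholesterol synthesis (median 0.05, adjusted p = 0.947) and fatty acid handling (median 0.28, adjusted p = 0.360). So were Notch pathway (median 0.60, adjusted p = 0.266), flow response (median 0.17, adjusted p = 0.839), unfolded protein response (median 0.01, adjusted p = 0.775), myeloid progenitor and blast (median 1.08, adjusted p = 0.200), neutrophil (median -0.28, adjusted p = 0.775) and monocyte and macrophage (median 0.74, adjusted p = 0.456). The remainder were megakaryocyte and platelet (median 1.54, adjusted p = 0.537), B cell (median -0.24, adjusted p = 0.537), T and NK cell (median 0.65, adjusted p = 0.200), marrow stromal and osteolineage (median 0.87, adjusted p = 0.395) and lung epithelium (median -0.54, adjusted p = 0.947). Median, mean and test differed in sign for venous endothelium (median -1.04, mean -0.46, test up), antigen presentation (median 0.01, mean -0.02, test up) and cholesterol synthesis (median 0.05, mean 0.21, test down). The same held for neutrophil genes (median -0.28, mean -0.38, test up) and lung epithelium (median -0.54, mean -0.36, test up). With library totals alone the neutrophil median turned positive, at 0.06.

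Among 5485 genes called in the marrow with at least 10 CPM in the higher group and no overlap between groups, the 8 largest rises were in genes almost absent from controls. Chance leaves 3 against 3 libraries without overlap for 10% of genes. Cpne7, a calcium-dependent membrane-binding protein (chromosome 8, 123117374 to 123135182, GRCm38), had 1 count over the 3 controls and 21.5 ± 7.23 CPM in AML (ratio 1334, counting interval 239 to 52714). Cpa3, a carboxypeptidase of mast cells, also had 1 count over the controls (ratio 1345, counting interval 241 to 53171), as had Mapk10, a stress kinase (ratio 1178, counting interval 211 to 46545). For Tarm1, a receptor of myeloid cells, the values were 1 count and a ratio 625, counting interval 112 to 24709, and for the noncoding RNA Platr14 1 count and a ratio 571, counting interval 102 to 22587. Soga3 had 2 counts over the controls (ratio 388, counting interval 107 to 3205). Single libraries carried some of these ratios. Those of Cpa3 and Tarm1 were 559.8 and 357 without marrow AML 2, and that of Tarm1 940.4 without marrow AML 3. Leaving out the control with the 1 count left bounds, against a floor of 3 counts, of 280.1 and 247 for Cpne7 and Mapk10 (marrow control 1), 137 for Tarm1 (control 2) and 319.6 and 136 for Cpa3 and Platr14 (control 3). Through lower depth alone, Cpa3, Tarm1, Platr14 and Soga3 were at 848, 394, 359.8 and 244 without marrow control 1, and Cpne7, Cpa3, Mapk10 and Platr14 at 877, 884, 774 and 375 without marrow control 2. Kcne3, a potassium channel subunit, and Fgf12, a growth factor homologue, had log2 fold changes of 8.21 ± 0.69 (adjusted p = 1.92e-05) and 8.12 ± 0.92 (adjusted p = 8.02e-05). The 8 largest falls ran from -6.30 ± 1.43 for Trim58, a ubiquitin ligase of red cell precursors (chromosome 11, 58640465 to 58652404, GRCm38; adjusted p = 0.00447), to -5.49 ± 1.61 for Rbm44 (adjusted p = 0.0170). Between them lay Slc13a5, a citrate transporter (-6.09 ± 1.47), Apol11b (-5.95 ± 1.46), Zfp808, a zinc finger gene (-5.93 ± 1.36), Strip2 (-5.87 ± 1.17), Mmp16, a membrane metalloproteinase (-5.78 ± 1.21), and Fam78a (-5.61 ± 1.08). Without marrow AML 1, Trim58, Slc13a5, Apol11b, Zfp808, Mmp16 and Rbm44 had fitted values of -11.37, -10.99, -12.06, -10.04, -8.72 and -11.54. Rbm44 no longer passed without marrow control 2 (log2 fold change -4.59, adjusted p = 0.0664). Counting ignored the strand, so genes that overlap others, such as Soga3, Kcne3 and Slc13a5, cannot be told from them.

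Lung AML libraries were compared with lung controls to ask how these samples, in which epithelial transcripts outnumbered endothelial ones, differ with leukaemia. Camera called 16 lists as lower, among them endothelial, antigen presentation and interferon response lists, and 6 as higher, although in many of them few genes passed. With an estimated correlation 7 kept the call, all lower, namely pan-endothelial, general capillary, aerocyte capillary, arterial, venous, Notch pathway and angiogenic sprouting. 16 of the 93 genes in these 7 lists lie in more than 1, among them 8 of 16 arterial, 6 of 12 general capillary and 8 of 24 sprouting genes, so these are not separate calls. Aplnr, the apelin receptor of capillary cells (chromosome 2, 85136225 to 85139923, GRCm38), fell from 155 ± 126 to 1.76 ± 0.852 CPM (mean ± SD, n = 3; log2 fold change -6.47 ± 0.87, adjusted p = 0.00529). Rhag, a membrane glycoprotein of red cells (chromosome 17, 40811126 to 40840754), rose from 1.20 ± 0.235 to 39.9 ± 32.5 CPM (log2 fold change 5.04 ± 0.57, adjusted p = 0.00250). Lox, which crosslinks collagen (chromosome 18, 52516067 to 52529867), rose from 18.5 ± 9.53 to 429.7 ± 119.7 CPM (log2 fold change 4.54 ± 0.45, adjusted p = 0.00161). By the same edgeR test 423 of 18147 genes passed, 212 higher and 211 lower, and 2995 had an unadjusted p under 0.05. The count depended on single libraries and on the tool. It was 218, 116 and 325 without lung control 1, 2 or 3, and 72, 248 and 83 without lung AML 1, 2 or 3, against 1614 by DESeq2, 2260 by limma-voom and 1239 in a fit of only the 6 lung libraries. The balance of directions turned as well, with 62 genes higher and 156 lower, 55 and 61, and 140 and 185 without lung control 1, 2 or 3. Without lung AML 1, 2 or 3 they were 50 and 22, 147 and 101, and 62 and 21. Library totals alone gave 182 higher and 273 lower.

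Of 20 pan-endothelial genes, 11 fell, with 20 adjusted over the list alone (median log2 fold change -3.21, camera adjusted p = 3.08e-25, or 0.0490 with an estimated correlation). Each of the 20 was higher in every lung control than in any lung AML library. For genes moving together this has a 5% chance. The list median was -2.46 without lung control 2, the library richest in these transcripts. Cdh5 went from 188 ± 143 to 15.9 ± 14.4 CPM (log2 fold change -3.56 ± 0.74, adjusted p = 0.0325), and Kdr, Eng, a TGF-beta co-receptor, and Clec14a, a surface lectin, had log2 fold changes of -3.96 ± 0.67, -3.16 ± 0.54 and -4.58 ± 0.80. Their adjusted p-values were 0.0150, 0.0153 and 0.0170. Among 12 general capillary genes, 8 fell, against 10 adjusted over the list alone (median log2 fold change -3.40, camera adjusted p = 3.84e-17, or 0.0435 with an estimated correlation). Plvap, a component of fenestral diaphragms, and Tmem100, a membrane protein of capillaries, fell alongside Aplnr (log2 fold change -4.17 ± 0.65, adjusted p = 0.0112, and log2 fold change -3.46 ± 0.57, adjusted p = 0.0138). Of 16 arterial genes, 5 fell, with 7 adjusted over the list alone (median log2 fold change -1.55, camera adjusted p = 2.26e-09, or 0.0256 with an estimated correlation). Among 16 Notch pathway genes, 3 fell, against 7 adjusted over the list alone (median log2 fold change -1.60, camera adjusted p = 1.59e-07, or 0.0256 with an estimated correlation). Hey1, a Notch target, was in both lists (log2 fold change -4.05 ± 0.48, adjusted p = 0.00262), with Dll4, a Notch ligand (log2 fold change -4.02 ± 0.75, adjusted p = 0.0224). Of 14 flow response genes, 4 fell, and adjusted over the list alone 1 rose and 9 fell (median log2 fold change -1.98, camera adjusted p = 8.00e-08, or 0.0758 with an estimated correlation). Klf2, a transcription factor induced by shear stress, fell (log2 fold change -2.56 ± 0.47, adjusted p = 0.0212). Among 24 angiogenic sprouting genes, 6 fell, and adjusted over the list alone 1 rose and 12 fell (median log2 fold change -0.97, camera adjusted p = 3.24e-10, or 0.0256 with an estimated correlation). Esm1, a marker of tip cells, fell (log2 fold change -2.74 ± 0.34, adjusted p = 0.00366). Kdr, Clec14a, Dll4 and Klf2 lost the call without lung AML 1 or 3 or lung control 2 (adjusted p from 0.0512 to 0.122). Eng and Tmem100 lost the call without lung AML 1 or 3 (adjusted p from 0.0663 to 0.0857). Plvap lost the call without lung AML 3 (adjusted p = 0.0656). Cdh5 lost the call without lung control 2 or lung AML 1 or 3 (adjusted p = 0.125, 0.0992 and 0.159), and its adjusted p without lung control 3 lay just above 0.05. Its log2 fold change without lung control 2 was -2.76.

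Camera called other vessel lists as lower, although few of their genes passed. Of 10 venous genes, 2 fell, with 5 adjusted over the list alone (median log2 fold change -1.31, camera adjusted p = 0.000288, or 0.0490 with an estimated correlation). Among 12 aerocyte capillary genes, 2 fell, against 5 adjusted over the list alone (median log2 fold change -1.47, camera adjusted p = 1.20e-05, or 0.0490 with an estimated correlation). Of 15 sinusoidal genes, 1 fell, with 4 adjusted over the list alone (median log2 fold change -1.05, camera adjusted p = 0.00504, or 0.0758 with an estimated correlation). Among 8 lymphatic genes, 0 fell, and adjusted over the list alone 2 fell (median log2 fold change -2.65, camera adjusted p = 0.00239, or 0.0605 with an estimated correlation). Of the lymphatic genes, 3 had an unadjusted p under 0.05 by edgeR, and 2 passed by DESeq2 and 4 by limma-voom. Of 27 niche factor genes, 2 rose and 7 fell, with 3 and 8 adjusted over the list alone (median log2 fold change -0.97, camera adjusted p = 0.00180, or 0.101 with an estimated correlation). Bmp6, a bone morphogenetic protein, fell (log2 fold change -4.16 ± 0.52, adjusted p = 0.00370), whereas Igfbp3 rose (log2 fold change 3.14 ± 0.52, adjusted p = 0.0138). Among 28 TGF-beta response genes, 2 fell, and adjusted over the list alone 1 rose and 7 fell (median log2 fold change -0.50, camera adjusted p = 0.00335, or 0.260 with an estimated correlation). Smad6, an inhibitor of BMP signalling, fell (log2 fold change -2.89 ± 0.34, adjusted p = 0.00262). Without lung control 3 that list lost its call (adjusted p = 0.0587). Of 18 stromal and osteolineage genes, 1 rose and 3 fell, with 1 and 6 adjusted over the list alone (median log2 fold change -0.33, camera adjusted p = 0.0487, or 0.358 with an estimated correlation). That call ended without lung control 3 (adjusted p = 0.379), lung AML 2 (0.0616) or lung AML 3 (0.159), and with a replicate block (0.0505). Igfbp3 lost the call without lung AML 1 or lung control 1 (adjusted p from 0.0586 to 0.0618).

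Camera called lists of immune recognition genes as lower, but few of their genes passed, and with an estimated correlation the calls ended. Of 21 antigen presentation genes, 4 fell, with 15 adjusted over the list alone (median log2 fold change -1.28, camera adjusted p = 4.55e-15, or 0.0605 with an estimated correlation). Psmb9 and Psmb10, subunits of the immunoproteasome, had log2 fold changes of -2.04 ± 0.34 and -1.23 ± 0.21 (adjusted p = 0.0139 and 0.0145). Among 39 interferon response genes, 6 fell, against 12 adjusted over the list alone (median log2 fold change -0.69, camera adjusted p = 1.17e-07, or 0.228 with an estimated correlation). Gbp7 and Gbp4 encode interferon-induced GTPases and fell (log2 fold change -2.01 ± 0.32 and -5.33 ± 0.97, adjusted p = 0.0114 and 0.0207). Of 14 T and NK cell genes, 0 fell, with 0 adjusted over the list alone (median log2 fold change -1.44, camera adjusted p = 1.08e-05, or 0.0605 with an estimated correlation). Of these, 4 had an unadjusted p under 0.05 by edgeR, and 3 passed by DESeq2 and 6 by limma-voom. Psmb9 and Gbp7 lost the call without lung AML 1 or 3 (adjusted p from 0.0501 to 0.0813). Psmb10 lost the call without lung AML 1 or 3 or lung control 2 (adjusted p from 0.0517 to 0.0818). Gbp4 lost the call without lung AML 1, 2 or 3 or lung control 2 (adjusted p from 0.0588 to 0.114).

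Camera called 6 lists as higher in lung AML, but few of their genes passed, and with an estimated correlation the calls ended. Of 14 erythroid genes, 4 rose, and adjusted over the list alone 4 rose and 3 fell (median log2 fold change 0.96, camera adjusted p = 0.00101, or 0.441 with an estimated correlation). Klf1 went from 0.738 ± 0.0456 to 10.9 ± 6.18 CPM (chromosome 8, 84901928 to 84905291, GRCm38; log2 fold change 3.88 ± 0.42, adjusted p = 0.00239), and Car1, a carbonic anhydrase, from 1.99 ± 0.382 to 23.1 ± 15.5 (log2 fold change 3.53 ± 0.49, adjusted p = 0.00619). Both stayed far below the marrow controls, at 836 ± 7.90 and 2202 ± 101 CPM. Among 34 proliferation genes, 1 rose, against 11 adjusted over the list alone (median log2 fold change 0.96, camera adjusted p = 1.45e-09, or 0.312 with an estimated correlation). Of 25 fatty acid handling genes, 2 rose, and adjusted over the list alone 4 rose and 1 fell (median log2 fold change 0.13, camera adjusted p = 0.00655, or 0.228 with an estimated correlation). The 2 that passed were Pdk4, a kinase that restrains glucose oxidation (log2 fold change 2.75 ± 0.31, adjusted p = 0.00250), and Angptl4, an inhibitor of lipoprotein lipase (log2 fold change 2.92 ± 0.36, adjusted p = 0.00366). Among 29 hypoxia and glycolysis genes, 2 rose, against 5 adjusted over the list alone (median log2 fold change 0.19, camera adjusted p = 0.00428, or 0.0605 with an estimated correlation). Bnip3 rose (log2 fold change 1.51 ± 0.27, adjusted p = 0.0173). Of 27 immediate early genes, 1 rose, with 1 adjusted over the list alone (median log2 fold change 0.37, camera adjusted p = 0.00603, or 0.402 with an estimated correlation). This list lost its call without lung control 2 (adjusted p = 0.0633) or lung AML 2 (0.0649). Among 38 ribosomal protein genes, 0 rose, against 0 adjusted over the list alone (median log2 fold change 0.22, camera adjusted p = 0.00175, or 0.677 with an estimated correlation). Of the ribosomal genes, 2 had an unadjusted p under 0.05 by edgeR, and 1 passed by DESeq2 and 3 by limma-voom. The call of that list ended without lung control 3 (adjusted p = 0.360). Bnip3 lost the call without lung AML 1 or 3 or lung control 2 (adjusted p from 0.0687 to 0.0800). Lung lists whose median, mean and test differed in sign were inflammatory activation (median 0.10, mean -0.08, test up), p53 targets (median 0.15, mean -0.07, test up) and myeloid progenitor (median -0.37, mean 1.45, test down), none of them called.

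Of 328 lung genes eligible by the same rule, the largest rises were in Trap1a, a tumour antigen (log2 fold change 6.74 ± 1.12, adjusted p = 0.0145), Rhag, Lox and Abcb4, a phospholipid transporter (log2 fold change 4.37 ± 0.53, adjusted p = 0.00318). Trap1a (chromosome X, 139333683 to 139338169, GRCm38) averaged 18.7 ± 18.0 CPM in lung AML, 0.171 ± 0.122 in lung controls, 223 ± 18.9 in marrow AML and 1.07 ± 1.51 in marrow controls. Then came Slc13a4, a sulfate transporter (log2 fold change 4.24 ± 0.78, adjusted p = 0.0209), Tfr2, a transferrin receptor (log2 fold change 4.002 ± 0.55, adjusted p = 0.00586), and Ermap, an erythroid membrane protein (log2 fold change 3.96 ± 0.69, adjusted p = 0.0170). The largest falls were in Cyp1a1, a monooxygenase (log2 fold change -8.43 ± 1.80, adjusted p = 0.0370), Glp1r, the receptor of an incretin hormone (log2 fold change -5.14 ± 1.11, adjusted p = 0.0383), and Ackr4, a scavenging chemokine receptor (log2 fold change -5.07 ± 0.55, adjusted p = 0.00239). Tnfsf10, a death receptor ligand, Pcdh12, a protocadherin of endothelium, and Wscd1 had log2 fold changes of -4.77 ± 1.02, -4.62 ± 1.003 and -4.60 ± 0.77. Of the 16 genes named here by size with Aplnr, Gbp4 and Klf1, only Rhag, Lox, Abcb4, Tfr2, Klf1, Aplnr and Ackr4 kept the call in each of the 6 runs that leave out 1 library. Trap1a lost the call without lung control 1 or 2 (adjusted p from 0.0581 to 0.0587). Slc13a4, Glp1r and Pcdh12 lost the call without any of the 6 lung libraries (adjusted p from 0.0512 to 0.184). Ermap lost the call without lung AML 1 or 3 or lung control 1, 2 or 3 (adjusted p from 0.0508 to 0.0863). Cyp1a1 and Tnfsf10 lost the call without lung AML 1, 2 or 3 or lung control 2 (adjusted p from 0.119 to 0.186). Wscd1 lost the call without lung AML 1 or 3 or lung control 2 (adjusted p from 0.0638 to 0.0815). Without lung control 2 the Cyp1a1 value was -5.16. DESeq2 gave no adjusted p for Cyp1a1 and Glp1r, and with a replicate block Tnfsf10 and Pcdh12 did not pass (adjusted p = 0.0660 and 0.0683). Pecam1 and Ptprc did not pass (log2 fold change -2.87 ± 0.80, adjusted p = 0.0919, and log2 fold change -0.66 ± 0.91, adjusted p = 0.837), but Pecam1 passed by DESeq2 (adjusted p = 0.00473) and with a replicate block (adjusted p = 0.0453).

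**Figure D2:**
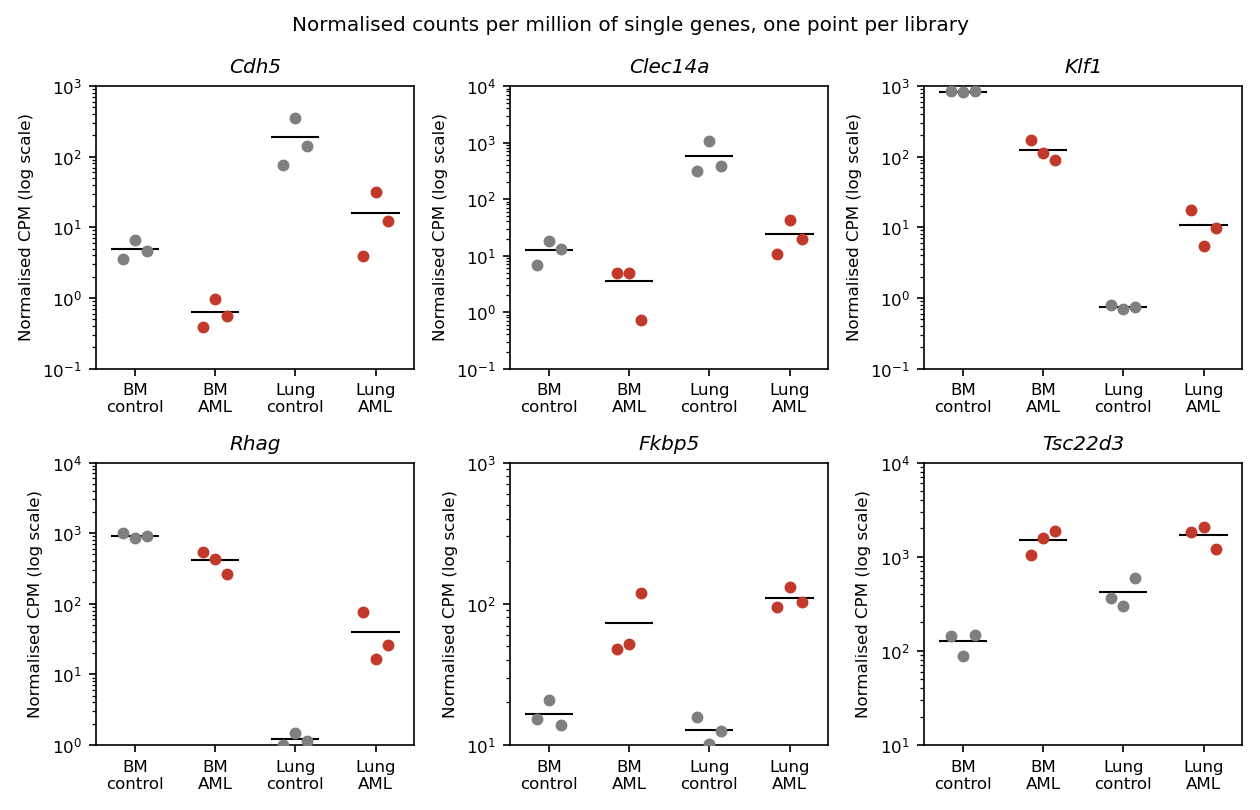
Normalised counts (CPM, log scale) of 6 genes, with 1 point per library and a line at each group mean. Cdh5 averaged 188 in lung controls and 15.9 in lung AML, Clec14a 578 and 24.2, Klf1 0.738 and 10.9, and Rhag 1.20 and 39.9.

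**Figure D3:**
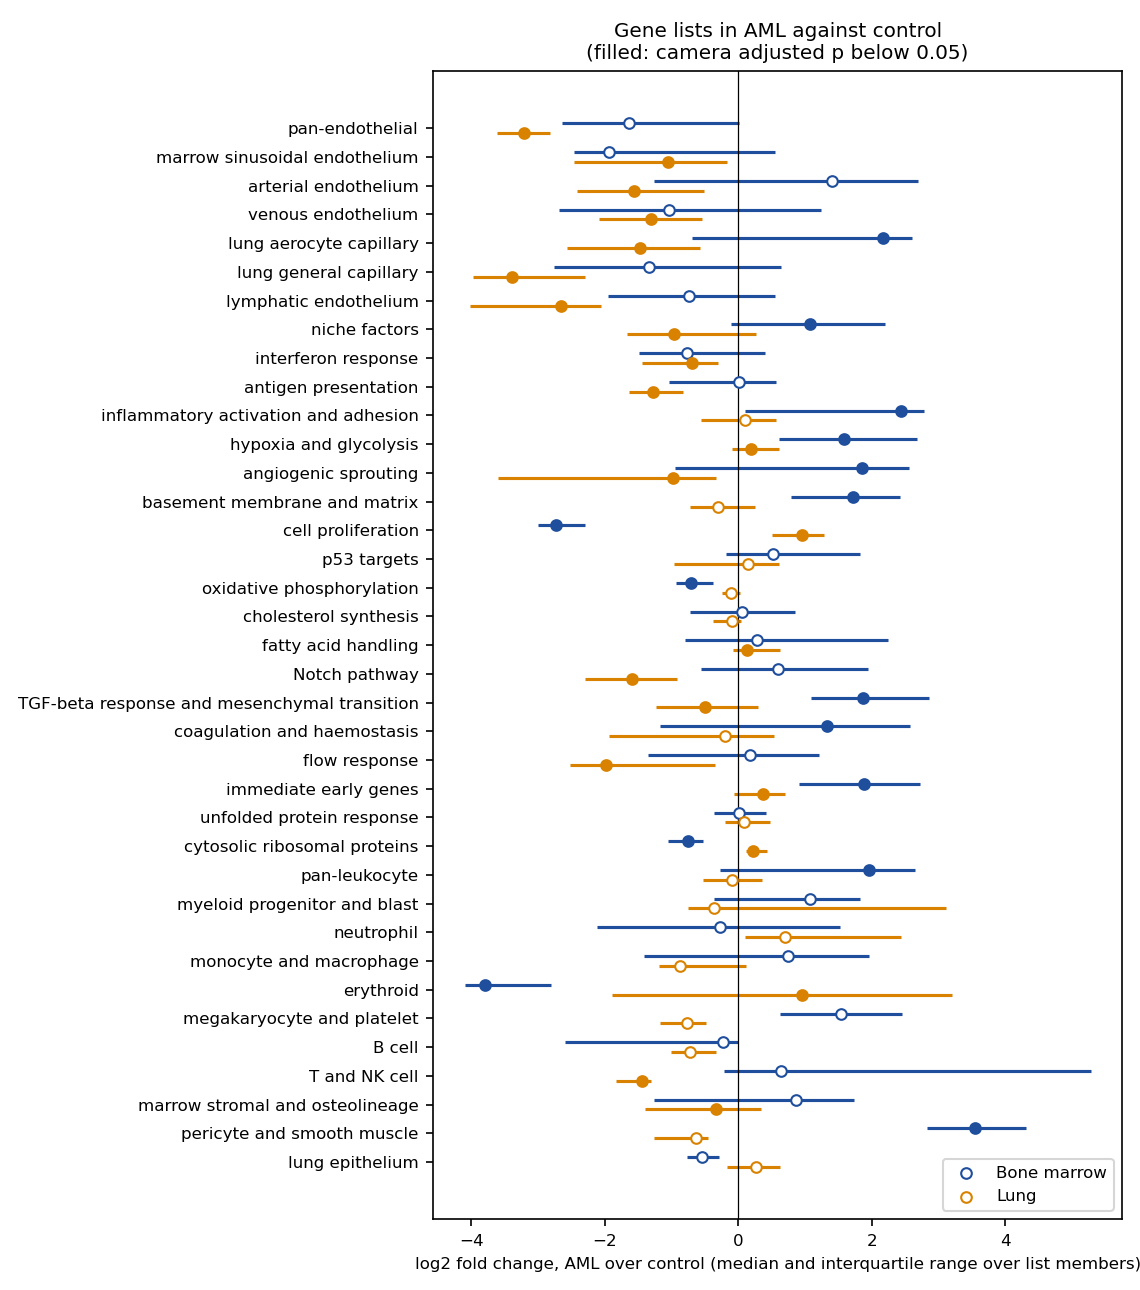
Median log2 fold change of each of 37 gene lists (points) with its interquartile range (lines), AML over control, in marrow and lung. Filled points had a camera adjusted p below 0.05, which held for 15 lists in the marrow and 22 in the lung.

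The AML effect in the marrow was set against that in the lung by an interaction test. Camera called lists of sprouting, matrix and TGF-beta response genes as upward in the marrow relative to the lung, and those of red cell precursor and proliferation genes as downward. With an estimated correlation only angiogenic sprouting and hypoxia and glycolysis kept the call, 2 of 22. Gja4, a gap junction protein of arteries, averaged 7.16 ± 2.61 and 99.9 ± 32.6 CPM in marrow controls and AML, and 82.6 ± 36.4 and 16.2 ± 5.47 in lung controls and AML (interaction log2 fold change 6.16 ± 0.61, adjusted p = 0.000149). Klf1 moved the other way, with an interaction of -6.63 ± 0.56 (adjusted p = 8.14e-05). The interaction passed for 5567 genes, 2642 upward and 2925 downward in the marrow relative to the lung. The median over all genes was -0.09 with TMM and 0.30 with library totals alone, which gave 3494 upward and 1756 downward. Upward calls also outnumbered downward ones with the filter of 5 CPM (2797 and 2174), against a 1.5-fold change (2073 and 1944), by DESeq2 (3309 and 3306) and without lung AML 2 (2231 and 2016).

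Of 24 angiogenic sprouting genes, 15 were upward and 2 downward, with 15 and 2 adjusted over the list alone (median log2 fold change 2.72, camera adjusted p = 6.90e-08, or 0.0493 with an estimated correlation). Esm1 and Angpt2 had interactions of 5.15 ± 0.48 and 5.11 ± 0.58 (adjusted p = 0.000125 and 0.000224). Among 29 hypoxia and glycolysis genes, 14 were upward and 2 downward, against 14 and 2 adjusted over the list alone (median log2 fold change 0.95, camera adjusted p = 9.83e-06, or 0.0493 with an estimated correlation). Of 28 TGF-beta response genes, 19 were upward, with 22 adjusted over the list alone (median log2 fold change 2.42, camera adjusted p = 4.45e-10, or 0.0538 with an estimated correlation). Among 28 basement membrane and matrix genes, 15 were upward, and adjusted over the list alone 19 upward and 1 downward (median log2 fold change 1.71, camera adjusted p = 3.13e-07, or 0.111 with an estimated correlation). Of 34 proliferation genes, 32 were downward, with 34 adjusted over the list alone (median log2 fold change -3.75, camera adjusted p = 3.77e-22, or 0.157 with an estimated correlation). Among 14 erythroid genes, 9 were downward, against 9 adjusted over the list alone (median log2 fold change -4.31, camera adjusted p = 2.45e-08, or 0.216 with an estimated correlation). Rhag had an interaction of -6.21 ± 0.73 (adjusted p = 0.000239). Of 20 pan-endothelial genes, 6 were upward, with 6 adjusted over the list alone (median log2 fold change 1.37, camera adjusted p = 0.00707, or 0.535 with an estimated correlation). Cdh5, Pecam1 and Ptprc did not pass (log2 fold change 0.66 ± 1.07, 1.32 ± 1.09 and -0.86 ± 1.30, adjusted p = 0.686, 0.396 and 0.663). Nor did Kdr and Dll4, lower in both tissues (adjusted p = 0.782 and 0.982). Without lung control 2 the Cdh5 value was -0.14 (adjusted p = 0.948), and without marrow AML 2 Ptprc passed at -4.35 (adjusted p = 0.00168).

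Among vessel and niche lists, arterial endothelium, aerocyte capillary, general capillary and niche factors were called as upward (camera adjusted p = 8.19e-05, 0.000125, 0.00168 and 9.54e-06). In that order, 9 of 16, 7 of 12, 5 of 12 and 12 of 27 genes passed upward, and 9, 7, 5 and 13 adjusted over the list alone, against 1 downward in arterial endothelium (adjusted p = 0.0663, 0.0814, 0.325 and 0.0546 with an estimated correlation). Upward calls also went to antigen presentation, inflammatory activation, Notch pathway and coagulation (camera adjusted p = 0.000125, 4.65e-06, 0.00168 and 0.0166). Here 10 of 21, 14 of 27, 6 of 16 and 7 of 18 genes passed upward, and 10, 16, 6 and 7 adjusted over the list alone, against 1 downward in inflammatory activation, 1 in Notch pathway and 1 in coagulation (adjusted p = 0.325, 0.0546, 0.0814 and 0.216 with an estimated correlation). Further upward lists were flow response, immediate early genes, pan-leukocyte, T and NK cell and pericyte and smooth muscle (camera adjusted p = 0.0159, 9.54e-06, 0.00168, 0.0211 and 4.68e-07). Among these lists 7 of 14, 16 of 27, 9 of 18, 4 of 14 and 12 of 14 genes passed upward, and 8, 17, 10, 5 and 12 adjusted over the list alone, against 1 downward in flow response (2 over the list alone), 1 in immediate early genes and 2 in pan-leukocyte (3 over the list alone) (adjusted p = 0.410, 0.216, 0.216, 0.319 and 0.216 with an estimated correlation). Downward lists were oxidative phosphorylation and ribosomal proteins (camera adjusted p = 0.00325 and 4.83e-05). They had 12 of 43 and 15 of 38 genes pass downward, and 12 and 19 adjusted over the list alone (adjusted p = 0.568 and 0.535 with an estimated correlation). Without marrow AML 2 or lung AML 2, the T and NK cell list lost its call (adjusted p = 0.0539 and 0.0641). Signs differed between median, mean and test for venous endothelium (median -0.36, mean 0.77, test up), fatty acid handling (median -0.11, mean 0.41, test up), myeloid progenitor (median 1.59, mean -0.97, test up) and B cell (median 0.25, mean -0.56, test down), none called. With library totals the medians of venous endothelium, fatty acid handling and unfolded protein response turned from -0.36, -0.11 and -0.11 to 0.07, 0.30 and 0.29.

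Genes named for the size of their interaction included Gata3, a transcription factor (log2 fold change 8.42 ± 1.01, adjusted p = 0.000260), Apln, the apelin peptide (log2 fold change 8.22 ± 1.67, adjusted p = 0.00398), and Dok2, a docking protein of blood cells (log2 fold change 7.62 ± 0.74, adjusted p = 0.000144), all upward. Gata3 averaged 0.362 ± 0.420, 14.3 ± 2.47, 18.5 ± 7.01 and 2.18 ± 0.715 CPM in marrow controls, marrow AML, lung controls and lung AML. Apln averaged 0.571 ± 0.429, 5.83 ± 5.08, 32.7 ± 12.7 and 1.09 ± 0.138 CPM in the same order, and Dok2 0.135 ± 0.102, 24.7 ± 8.54, 3.94 ± 1.14 and 3.49 ± 0.893. Downward genes were Add2, a membrane skeleton protein of red cells (log2 fold change -7.85 ± 1.01, adjusted p = 0.000366), Ermap (log2 fold change -7.17 ± 0.92, adjusted p = 0.000365), and Robo2, a guidance receptor (log2 fold change -6.98 ± 1.22, adjusted p = 0.00184). In the same order of groups, Add2 averaged 294 ± 96.7, 13.5 ± 9.73, 0.199 ± 0.106 and 2.09 ± 1.42 CPM, Ermap 822 ± 161, 89.2 ± 69.3, 0.675 ± 0.104 and 10.5 ± 5.23, and Robo2 8.80 ± 4.80, 0.307 ± 0.366, 7.07 ± 3.88 and 28.6 ± 5.20. Ltf and Ngp, proteins of neutrophil granules, averaged 6.08 ± 10.5, 0.0797 ± 0.0882, 1.10 ± 0.744 and 29.8 ± 25.02, and 11.8 ± 19.8, 2.53 ± 3.97, 0.153 ± 0.169 and 37.4 ± 31.1 CPM, and rested on marrow control 1. Without it the interactions were -3.29 and -5.15 (adjusted p = 0.470 and 0.115), against -10.85 and -10.13 with all libraries. Ngp also lost the call without lung control 2 or 3 (adjusted p = 0.0516 and 0.0558), and both lost it with a replicate block (adjusted p = 0.0597 and 0.0742). The other genes picked by size had 3 counts or fewer over 1 group or more, so no interaction is given for them here. Of those upward, Cfap53 averaged 0 ± 0, 1.08 ± 1.03, 18.2 ± 17.5 and 4.68 ± 1.40 CPM, Cpne7 0.0155 ± 0.0269, 21.5 ± 7.23, 0.593 ± 0.261 and 1.90 ± 0.530, and Mapk10 0.0155 ± 0.0269, 19.96 ± 5.51, 0.874 ± 0.735 and 3.17 ± 1.19. Cpa3 averaged 0.0200 ± 0.0346, 21.8 ± 20.9, 0.714 ± 0.320 and 3.06 ± 2.44 CPM, and Platr14 0.0200 ± 0.0346, 10.5 ± 3.36, 0.0686 ± 0.0535 and 0.153 ± 0.156. Of those downward, Elane averaged 29.1 ± 30.2, 2.92 ± 3.29, 0 ± 0 and 3.38 ± 3.14 CPM, Pklr 79.4 ± 9.38, 16.2 ± 13.0, 0.0384 ± 0.0665 and 1.62 ± 0.753, and Eya4, a developmental phosphatase, 6.41 ± 2.07, 12.8 ± 4.88, 0 ± 0 and 1.32 ± 0.889.

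Calls shared by the marrow and the lung comparison went in like and in opposite directions. Of the genes called in both, 91 were higher in both, against 43.2 if the calls were independent, and 55 were lower in both, against 49.6. A further 89 were higher in marrow and lower in lung, against 43.0, and 58 lower in marrow and higher in lung, against 49.8. All of these opposite calls also passed the interaction test, as did 26 of those higher in both and 6 of those lower in both. Pdk4 was higher in both tissues (log2 fold change 2.63 ± 0.31 in marrow and 2.75 ± 0.31 in lung), and so was Angptl4 (2.81 ± 0.36 and 2.92 ± 0.36). Aplnr was lower in both (-3.80 ± 0.90 and -6.47 ± 0.87). These 3 genes were chosen for this comparison of tissues after their values were seen. Across the 18147 genes, which are not independent replicates, the log2 fold changes of the 2 tissues had a Pearson correlation of 0.119 and a Spearman correlation of 0.0161.

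**Figure D4:**
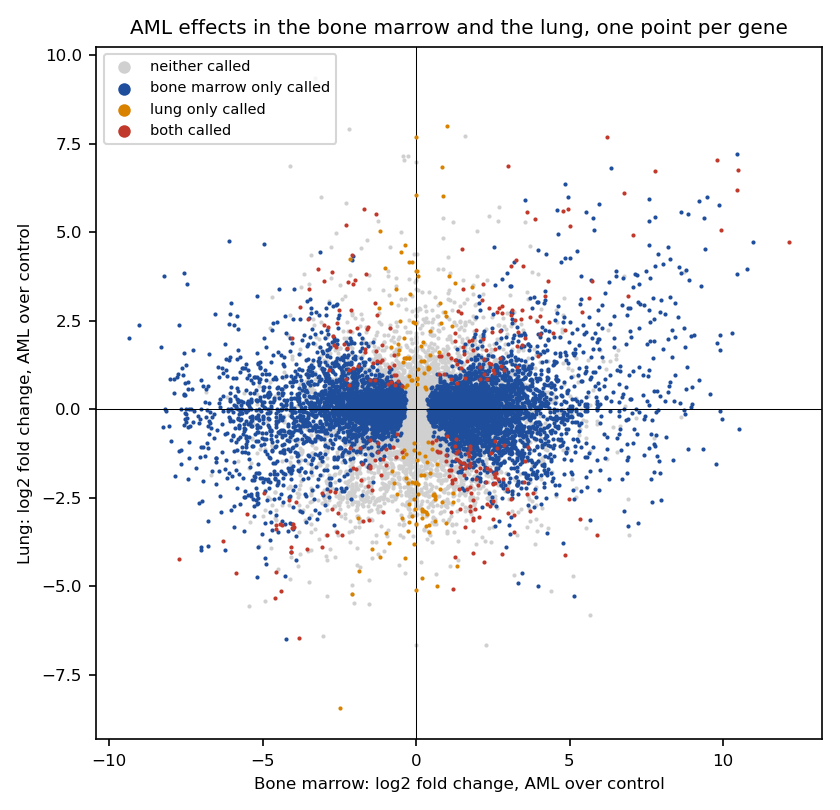
Log2 fold change of AML over control in the marrow (horizontal) and the lung (vertical), with 1 point per gene coloured by the comparison that called it. Genes called in both lay in each of the 4 corners, with 91 higher in both and 55 lower in both.

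Marrow controls were compared with lung controls as the difference between tissues without leukaemia. Camera called the lists of red cell precursor, proliferation, ribosomal and stromal genes as higher in the marrow libraries, and those of epithelial, endothelial and leukocyte genes as higher in the lung libraries. With an estimated correlation camera called 0 of these lists, against 23 at the preset correlation and 35 by directional fry. Klf1 differed by 10.14 ± 0.53 (adjusted p = 2.21e-07), and Ibsp, a bone matrix protein, by 8.82 ± 0.61 (adjusted p = 8.54e-07). Emp2 and Ager, a receptor of alveolar type 1 cells, were lower in marrow (log2 fold change -4.95 ± 0.22, adjusted p = 1.71e-07, and log2 fold change -7.12 ± 0.76, adjusted p = 1.28e-05). The edgeR test passed 11645 genes, 5343 higher and 6302 lower in marrow controls (5381 and 6243 with library totals alone). The median log2 fold change was -0.20 over all genes tested and -0.18 with library totals.

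Of 14 erythroid genes, 14 were higher, with 14 adjusted over the list alone (median log2 fold change 8.09, camera adjusted p = 5.14e-09, or 0.277 with an estimated correlation). Among 34 proliferation genes, 34 were higher, against 34 adjusted over the list alone (median log2 fold change 6.75, camera adjusted p = 1.59e-27, or 0.277 with an estimated correlation). Higher in marrow controls were also oxidative phosphorylation, ribosomal proteins and stromal and osteolineage genes (camera adjusted p = 4.38e-14, 1.45e-19 and 0.000793). Of these, 42 of 43, 38 of 38 and 10 of 18 genes passed as higher, and 43, 38 and 10 adjusted over the list alone, against 5 lower in stromal and osteolineage genes (adjusted p = 0.277, 0.277 and 0.277 with an estimated correlation). Of 20 pan-endothelial genes, 19 were lower, with 20 adjusted over the list alone (median log2 fold change -4.46, camera adjusted p = 0.000252, or 0.379 with an estimated correlation). Cdh5 differed by -5.26 ± 0.81 (adjusted p = 0.000181), and Pecam1 by -5.48 ± 0.91 (adjusted p = 0.000318). Among 18 lung epithelium genes, 18 were lower, against 18 adjusted over the list alone (median log2 fold change -7.16, camera adjusted p = 3.87e-07, or 0.309 with an estimated correlation). Vessel lists called as lower were arterial, aerocyte capillary, general capillary, angiogenic sprouting and Notch pathway (camera adjusted p = 0.00274, 0.000252, 0.0183, 0.00378 and 0.00378). In this order, 12 of 16, 12 of 12, 10 of 12, 16 of 24 and 14 of 16 genes passed as lower, and 13, 12, 10, 17 and 14 adjusted over the list alone, against 2 higher in arterial, 1 in general capillary and 2 in angiogenic sprouting (adjusted p = 0.277, 0.277, 0.468, 0.277 and 0.277 with an estimated correlation). Leukocyte lists were lower too, namely pan-leukocyte, monocyte and macrophage, B cell and T and NK cell (camera adjusted p = 0.0173, 0.00812, 0.00513 and 0.00329). From each, 14 of 18, 14 of 18, 10 of 13 and 13 of 14 genes passed as lower, and 14, 14, 10 and 13 adjusted over the list alone, against 4 higher in pan-leukocyte and 1 in monocyte and macrophage (adjusted p = 0.331, 0.277, 0.277 and 0.281 with an estimated correlation). Ptprc differed by -2.89 ± 0.98 (adjusted p = 0.0224), and lost the call without marrow control 2 or 3 (adjusted p = 0.0632 and 0.0774).

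The remaining lists called as lower were antigen presentation, cholesterol synthesis and inflammatory activation (camera adjusted p = 0.000363, 0.000381 and 0.0358). There, 15 of 21, 17 of 21 and 15 of 27 genes passed as lower, and 15, 18 and 15 adjusted over the list alone, against 4 higher in inflammatory activation (adjusted p = 0.336, 0.277 and 0.288 with an estimated correlation). With them stood basement membrane, TGF-beta response, coagulation and flow response (camera adjusted p = 0.0183, 0.0206, 0.0251 and 0.0431). In these lists 15 of 28, 16 of 28, 11 of 18 and 11 of 14 genes passed as lower, and 15, 16, 11 and 11 adjusted over the list alone, against 4 higher in basement membrane, 3 in TGF-beta response, 2 in coagulation and 2 in flow response (adjusted p = 0.350, 0.334, 0.277 and 0.468 with an estimated correlation). Without marrow control 2, inflammatory activation, basement membrane, TGF-beta response and coagulation lost their calls (adjusted p = 0.0601, 0.0567, 0.0573 and 0.0593). Flow response lost its call without marrow control 1 or 3 (adjusted p = 0.0584 and 0.0572). H2-Ab1, a class II antigen presentation gene, differed by -6.01 ± 0.50 (adjusted p = 2.49e-06), and Hmgcs1, an enzyme of cholesterol synthesis, by -3.60 ± 0.33 (adjusted p = 4.57e-06). The myeloid progenitor list, not called (adjusted p = 0.575), had a median of -1.17, a mean of 1.29 and a test downward.

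Of 7924 eligible genes, the largest differences upward in marrow controls were in Elane, neutrophil elastase, which had 0 counts over the lung controls and was at least 781-fold higher in marrow controls. These bounds take 3 counts over the group as the floor. Rnf212 was at least 311-fold and Slc13a5 at least 267-fold higher. Tac2, a tachykinin precursor, had 1 count over the lung controls (ratio 3742, counting interval 671 to 147856), and Pklr, the pyruvate kinase of red cells, 3 (ratio 2028, counting interval 694 to 9838). Hemgn, Cldn13, a claudin, and Redrum, a noncoding RNA of red cell development, had log2 fold changes of 10.85 ± 1.14, 10.75 ± 1.22 and 10.70 ± 0.64. In the other direction, Cfap53, a gene of motile cilia, had 0 counts over the marrow controls and was at least 335-fold lower there. Frmpd2, Dcdc2a, Lrrc43 and Ankrd66 were at least 258-, 235-, 211- and 185-fold lower. Lrrc71 and Upk3b, a uroplakin of mesothelium, had 1 count each over the marrow controls (ratio 1232, counting interval 221 to 48688, and ratio 1046, counting interval 187 to 41328), and Sntn, a cilium tip protein, 3 (ratio 908, counting interval 310.3 to 4403). Single libraries carried many of these values. Without marrow control 1 the Elane bound was 292, and without lung control 1 the bounds of Cfap53, Frmpd2, Dcdc2a, Lrrc43 and Ankrd66 were 159, 141, 95.3, 85.0 and 85.4. The ratios of Lrrc71, Sntn and Upk3b without lung control 1 were 574, 392.3 and 594. Without the library that held the few counts, bounds were 820.4 and 1334 for Tac2 and Pklr (lung control 2), and 269.9, 597 and 229 for Lrrc71, Sntn and Upk3b (marrow control 2). Lower depth alone moved others. Elane, Rnf212 and Slc13a5 were at 514, 204 and 175 without lung control 2, and with Tac2 and Pklr at 503, 200.3, 172, 2413 and 1308 without lung control 3. Cfap53, Frmpd2, Dcdc2a, Lrrc43 and Ankrd66 were at 211, 162, 148, 133 and 117 without marrow control 1 and at 219.9, 169, 154, 139 and 122 without marrow control 2, and Lrrc71, Sntn and Upk3b at 776, 572 and 659 without marrow control 1.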

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

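The tests on endothelial and leukaemia-associated transcripts below were chosen only after the result was seen, and the interaction test and the splits of the libraries were planned. The interaction results are listed because the AML effect differed between marrow and lung by a test of the difference itself. It was called for 5567 genes, and 1 of 60 splits of the libraries within each tissue, the real one, gave as many. In 7 drawn splits that kept the real marrow groups and split the lung libraries otherwise, 3468 to 5284 genes were called, the latter being the highest other count. Splits with other marrow groups gave at most 7, so the count follows the marrow groups, and the 10 splits of those are too few for a share under 0.05. For the marrow, lung and tissue comparisons the splits, 10 each, are too few for a share under 0.05, and only 1, the real one, gave as many calls as the 7957, 423 and 11645 found. The highest other counts were 3, 0 and 0.

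In opposite directions in marrow and lung, and with the interaction called, stood 147 genes. Of the 35 genes named in the marrow or lung comparison, 20 had a called interaction. The hypoxia and glycolysis list had a median interaction of 0.95 and the angiogenic sprouting list of 2.72, both upward in marrow relative to lung. Gene by gene, the fitted interactions upward were 9.63 for Cfap53, 8.42 for Gata3, 8.25 for Cpne7, 8.22 for Apln, 7.95 for Mapk10, 7.81 for Cpa3, 7.64 for Platr14 and 7.62 for Dok2. Downward they were -12.66 for Elane, -10.85 for Ltf, -10.13 for Ngp, -7.85 for Add2, -7.50 for Pklr, -7.17 for Ermap, -7.00 for Eya4 and -6.98 for Robo2. The fitted values of Cfap53, Cpne7, Mapk10, Cpa3, Platr14, Elane, Pklr and Eya4, with 0 to 3 counts over a group, depend on the prior count and are no bounds. Without marrow control 1 those of Ltf and Ngp were -3.29 and -5.15 (adjusted p = 0.470 and 0.115).

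Libraries labelled as endothelial held few endothelial transcripts, fewest among the lung libraries in lung AML. That 1 control library rich in them made the lung difference is argued against, since without lung control 2 the median log2 fold change of the pan-endothelial list was -2.46 (interquartile range -2.80 to -2.20), against -3.21 with it. More RNA of lung epithelial cells, which a sort on VE-cadherin would remove, as the whole cause of the lung difference is argued against, since it would dilute other cells alike, but over 10 lists for these the lowest lower quartile was -1.89 (erythroid), above the pan-endothelial upper quartile of -2.82. A lower share of endothelial cells in lung AML cannot be told apart from lower expression in them, because all 20 genes had negative log2 fold changes (11 called), but with library means of the list removed their differences had an SD 2.38 times the standard error, which other cells holding some of them would also give. Why both tissues held few endothelial transcripts, and whether leukaemia or the collection of the cells lowered them in lung AML, stays open and was not tested.

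Transcripts that marrow AML libraries held at 10 CPM or more and all controls below 1 CPM also appeared in lung AML, at a median ratio of 0.0449 to marrow AML (interquartile range 0.0287 to 0.0716, 22 genes). Carry-over of reads from the marrow AML libraries is argued against, since 6 marrow stromal genes had a median ratio of -1.80e-05 and a highest of 0.00455, and Ibsp, at 1696 CPM in marrow AML, was at 2.68 in lung controls and 2.83 in lung AML. Cells holding these transcripts may be a source, but whether they are leukaemia cells was not tested. For 77.3% of the set (17 genes) every lung AML library lay above every lung control. This held for 1 stromal gene and 18.2% of all genes tested. Chance gives 5% per gene, or for all if they move together, and more in this set, chosen for low lung control values. The median ratio was 0.0795, 0.0380 and 0.0446 in lung AML 1, 2 and 3, and 6 of the genes were called in the lung.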

How the results depend on the processing

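Scaling by library totals alone was chosen only after the result was seen, and the other tests here were planned. Counts of called genes in the marrow, interaction and tissue comparisons stayed within 1.5 times the main count under every alternative run, although the genes are not all shared. In the lung, the count of 423 became 123 against a 1.5-fold change, 1239 with only the 6 libraries compared, 2260 by limma-voom and 1614 by DESeq2. The 1.5-fold test asks for more than a difference from 0, and for the others the cause was not tested. Leaving out 1 library gave 6418 to 8589 called genes in the marrow, 72 to 325 in the lung (lowest without lung AML 1, highest without lung control 3), 4181 to 6417 for the interaction and 10374 to 10865 between tissues. With a replicate block, in which the number of a library is a term of the model, the counts were 7253, 331, 4924 and 11255. A block within condition gave 4161 for the interaction and 10469 between tissues.

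Of 37 lists, camera called 15 in the marrow, 22 in the lung, 22 for the interaction and 23 between tissues, but 1, 7, 2 and 0 with an estimated correlation between genes, which widens the test. In the same order, directional fry called 21, 17, 22 and 35, and mixed fry, which does not ask for 1 direction, 35, 27, 36 and 37. Without 1 library, camera called 15 to 16, 20 to 25, 21 to 23 and 19 to 25 lists. The correlation of AML effects between tissues, 0.119, was 0.0727 to 0.143 without 1 library, with a jackknife standard error of 0.0632. List members were examined called or not. Of these, 9 of 141 in marrow, 44 of 130 in lung and 12 of 135 for the interaction lost a call without some library.

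Each comparison named 19 genes by size or as checks, called or not. Direction and status held with each library left out for 16 (marrow), 9 (lung), 15 (interaction) and 18 (tissues). By DESeq2 they held for 19, 16, 19 and 19, and with its size factors for all. In the marrow, limma-voom passed 0 of 20 pan-endothelial, 3 of 12 aerocyte capillary and 2 of 12 general capillary genes, against 9, 8 and 7 by edgeR. Of called list members, 2 changed sign. In the marrow, Ltf ran from -7.68 to 1.46 over the libraries left out, with the positive value without marrow control 1 (adjusted p = 0.577). Gzmb ran from -2.90 to 9.82 in the marrow and from -1.46 to 11.26 for the interaction, negative without marrow AML 2 (adjusted p = 0.245 and 0.485). Ltf was at 18.2 CPM in marrow control 1 and at most 0.0502 in the other controls, and Gzmb at 13.9 CPM in marrow AML 2 and at 0 in the other AML libraries, so these single libraries carried the values. Fitted values of such genes, with few counts over a group, are no bounds. In the simulation, with few genes changed, at most 12.4% of 2-fold changes were recovered, so such changes can pass uncalled. With many calls the share may differ.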

Other observations

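The tests and the gene list of this part were chosen only after the result was seen. Several genes known to respond to glucocorticoids were higher in AML libraries of both tissues. Fkbp5, a chaperone that binds the glucocorticoid receptor, differed by 2.13 ± 0.35 in marrow and 3.09 ± 0.36 in lung (log2 fold change ± SE, n = 3), and Fmo2, a monooxygenase, by 4.19 ± 0.27 and 3.21 ± 0.26. Glul, glutamine synthetase, differed by 1.26 ± 0.20 and 1.92 ± 0.20, Tsc22d3, a transcriptional regulator induced by glucocorticoids, by 3.56 ± 0.36 and 2.02 ± 0.34, and Klf9, a transcription factor, by 2.50 ± 0.23 and 1.10 ± 0.22. By edgeR these 5 genes passed in both tissues (adjusted p = 0.0293 at most), but in lung Tsc22d3 lost the call without control 1, control 2 or AML 1 (adjusted p = 0.0666, 0.0661 and 0.0646). Klf9 lost it when any 1 of the lung libraries except control 3 was left out (adjusted p = 0.0781 to 0.128, highest without control 2). Sgk1, a kinase of the same list, rose in marrow (3.11 ± 0.31) and not in lung (-0.07 ± 0.29), with an interaction of 3.18 ± 0.42 (adjusted p = 0.000413).

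As a hypothesis, a glucocorticoid response in both tissues may accompany AML or the transplantation in these libraries. A list of 20 such genes left out Fkbp5, Fmo2, Glul, Nampt and Angptl4, seen first, and Pdk4, which ranked with them in lung. Its median log2 fold changes were 2.65 in marrow and 1.14 in lung. The lower was at percentile 100 of 10000 random lists matched on expression (also with Pdk4), which genes moving together can also reach. Called higher were 17 and 6 genes. In lung only Slc10a6 of these kept the call with each library left out, since without lung control 2, among other libraries for all but Map3k6, it was lost for Tsc22d3, Klf9, Cebpd, Sult1a1 and Map3k6 (the last 3 at adjusted p = 0.119, 0.102 and 0.0512), and in marrow Hif3a lost it without control 1, control 3, AML 1 or AML 3 (adjusted p = 0.107, 0.0527, 0.0521 and 0.0814). Stress of tissue handling stays open as a cause. In lung the upper quartile of the immediate early genes, 0.713, lay below the list median, but the list was chosen after seeing the result. In marrow that quartile, 2.74, lay above the list median and the immediate early median, 1.89, below it. A change in the cell makeup cannot be told apart from a response, because the list in lung control 2, with the most endothelial transcripts, differed from the other controls by 0.0381, which leaves open what other cells hold.

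Transcripts of lung epithelium were also present in marrow libraries. The 6 most abundant lung epithelium genes, Sftpc, Sftpa1, Cbr2, Sftpd, Sftpb and Napsa, had median levels of 0.191%, 1.23% and 0.293% of the lung mean in marrow controls 1, 2 and 3. In marrow AML 1, 2 and 3 the levels were 0.165%, 0.125% and 0.934%.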
